A study of Macaca mulatta with 54 samples.

How the data were processed

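Tissue from M1, PMd and PMv of both hemispheres of 9 rhesus macaques was dissected by sulcal landmarks, with 50 to 150 mg per piece, per the labels. Per the labels' protocols total RNA was extracted, with integrity numbers from 8.0 up to 9.5, and 0.1 µg of each was labelled with the dye Cy3 for 1-colour Agilent arrays. The group of each sample (area, side and time after the lesion) and the replicate number were taken from the labels. Within a time group a replicate number marks 1 animal across the 6 areas.

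The authors deposited 1 scanner file per array, written by Agilent Feature Extraction 9.5.3.1 per the file headers, while the submitters' processing notes name version 9.1. Per the file headers the arrays carry an Agilent rhesus design, and each of its 20217 probes outside the controls is spotted 2 times. The intensity used here is the processed signal, which per the file headers is background-subtracted, and which is not normalized between arrays. The authors also deposited a value table for the whole series. Its values, as deposited by the authors, are on a log2 scale with a centring that the labels do not describe, since differences between arrays of 1 area and side equalled the log2 differences of the scanner signals (correlation and slope of 1 over probes well above background on all arrays), up to 1 shift per array. Each probe of that deposited table is centred within each area and side on a value not stated in the sources used here, and the medians of its arrays lay between −0.066 and 0.052. It therefore served as an alternative only for comparisons between time groups.

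Spots marked as outliers (1647 of 2183436) were left out and the spots of a probe were averaged as log2 values. The 75th percentile of each array over the probes outside the controls was subtracted. 5 probes with no usable spot on some array were left out. A probe was kept if every spot was well above background on all 3 arrays of at least 1 of the 18 groups, which 14631 probes passed. The brightest probe of each accession was taken, which left 14008 features. 12842 probes were well above background on all 54 arrays. No pair of arrays held identical values. A feature not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group against the mean of, per array, the higher of its own signal and the lowest signal among probes well above background.

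The files hold accessions and no gene names. Of the 20217 probes, 8 had an accession in the reference table of rhesus genes used here, 7 with an uncharacterised locus name and 1 with a symbol, and 16722 carried accessions that begin with NM, 859 only their own probe identifier and the rest accessions of other kinds. For that reason the 26 gene lists written before the data were examined could not be tested, nor could the genes chosen by name in advance be reported. The rule for named features, fixed at the same time, took those with the largest change among the features with an adjusted p under 0.05 whose groups did not overlap, and set accessions aside to be counted. At most 2 accessions that rose and 2 that fell are given here, which departs from that rule.

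Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. Time groups were compared on the mean of the 6 areas of each animal and in each area and side, with the 3 groups in 1 fit. The area-by-time F test used all 54 arrays with the animal as a block. Contrasts of M1 against the premotor areas, of PMd against PMv and of left against right within each area were added to that model after the data were seen. Areas of naive animals were compared on the mean of left and right with the animal as a block, and sides on the left minus right difference of each animal. The 6 areas of an animal are paired because they come from the same animal, and deviations of such arrays from their group means correlated with r between 0.52 and 0.89. Spike-in levels were compared by two-sided exact permutation tests over the means of the animals.

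The steps were tested on simulated data of 14008 features with the spread of the real arrays and 200 changed features. Each simulated animal had 1 shift shared by its arrays, and each array had independent noise. No correlation within an area, side or slide of an animal was put in, while left and right of an area had an estimated correlation of 0.35 in the real data. The shares and false calls below, above all for the area-by-time and left minus right tests, hold for that simpler case. For the mean of 6 areas at 2 weeks, 46.3%, 77.6% and 86.4% of features changed 1.5-fold, 2-fold and 4-fold were called, with 13 false calls. For right PMd at 2 weeks the shares were 31.3%, 74.6% and 92.4%, with 6 false calls. For M1 against PMd in naive animals they were 83.6%, 98.5% and 100%, with 13 false calls. For the area-by-time test at 2 weeks, with a change in M1 alone, they were 73.1%, 97.0% and 100%, with 21 false calls. For the left minus right change at 2 weeks, placed on the left side of every 2-week animal, they were 89.6%, 97.0% and 100%, with 7 false calls. For the left against right difference of naive animals they were 95.5%, 100% and 98.5%, with 10 false calls.

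Scan day and slide were taken from the file headers. The arrays were scanned on 3 days and lay on 16 slides. The first day held 26 arrays, namely all naive arrays, 2-week animal 2 and the M1 arrays of 2-week animal 1. The second day held the other 10 arrays of 2-week animals and the third day the 18 arrays of 3-month animals. Each slide held 1 time group, so the slide could not be a fixed factor in the comparisons of time groups and entered as a random block. M1 and PMd of 1 animal shared a slide in 2-week animal 2 and in 3-month animals 2 and 3.

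Alternatives planned before the data were examined were normexp background correction (offset 50), quantile normalization, the authors' value table, no filter or a stricter filter on dim probes, the mean of the probes of an accession, array weights, 1 fit of all 54 arrays with the animal as a random block, the replicate number as a block, other blocks for the area tests, and leaving out each animal. The normexp step used the median signal and the median background of a spot, the columns held by the files, in place of the mean signal. Scan day as a factor, the shared scan day alone, the slide as a random block, left and right as a correlated pair, 1 value per animal, separate naive animals as controls and the comparison of areas on the naive arrays alone were added after seeing the data. With scan day as a factor a 2-week comparison rests on the lesioned animals scanned with the naive arrays, which were 2 for M1 and 1 for PMd and PMv.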

Results

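Gene expression was measured in the motor cortex of 9 rhesus macaques. 3 animals were intact, here called naive. In the other animals the lateral corticospinal tract, the main descending pathway from motor cortex to the spinal neurons that move the hand, had been cut in the cervical spinal cord. 3 of them were examined 2 weeks and 3 were examined 3 months after the lesion, a period over which hand movements were trained and scored daily. From each animal 6 pieces of cortex were taken, namely the primary motor cortex (M1, its forelimb region), the dorsal premotor cortex (PMd) and the ventral premotor cortex (PMv) of the left and the right hemisphere. Each piece was hybridised to 1 single-colour array, which gave 54 arrays in 18 groups of 3. The labels do not give the side of the lesion, so left and right are reported as such. The level of a feature, which is the brightest probe of a transcript accession, is its log2 signal minus the 75th percentile of its array. 14008 features were bright enough to test. Between 67.3% and 79.5% of the probes of an array were well above background, and 3 animals per group limit the precision.

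The animal and the time group accounted for most of the variation between arrays, and the cortical area for less. The closest array to each of the 54 arrays came from the same animal, against 9.43% expected by chance, and for 43 of them it was the same area of the opposite hemisphere. The chance value is for the animal alone. Left and right of an area of an animal always lay on the same slide, so the closeness of the hemispheres cannot be told apart from the slide. For the median feature the time group took up 23.7% of the variance (3.77% expected from its degrees of freedom alone), the animal within its time group 35.6% (11.3%), the area 4.34% (3.77%), the side 0.513% (1.89%) and the area-by-time term 2.80% (7.55%). These expected shares count the 54 arrays as independent. Time groups differ only between animals, so 23.7% on 2 degrees of freedom is to be read against 35.6% on 6, and not against 3.77%. The naive, 2-week and 3-month arrays did not overlap in the plane of the first and second principal components. On the second component the 2-week arrays lay between −28.7 and −8.77 and the naive arrays between −4.76 and 19.3, and the 3-month arrays lay between 6.51 and 15.9. The 8 arrays of 2-week animals that were scanned on the same day as all naive arrays lay between −22.2 and −13.9 there. On the first component these 8 arrays lay between −15.3 and 8.51, which overlapped the naive arrays (−26.4 to −12.4). The 10 arrays of 2-week animals scanned on another day lay between −1.997 and 28.8, and the 3-month arrays between 4.85 and 24.4. Scan day mostly followed the animal, so the first component does not tell scan day apart from the animal or the time group.

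**Figure D1:**
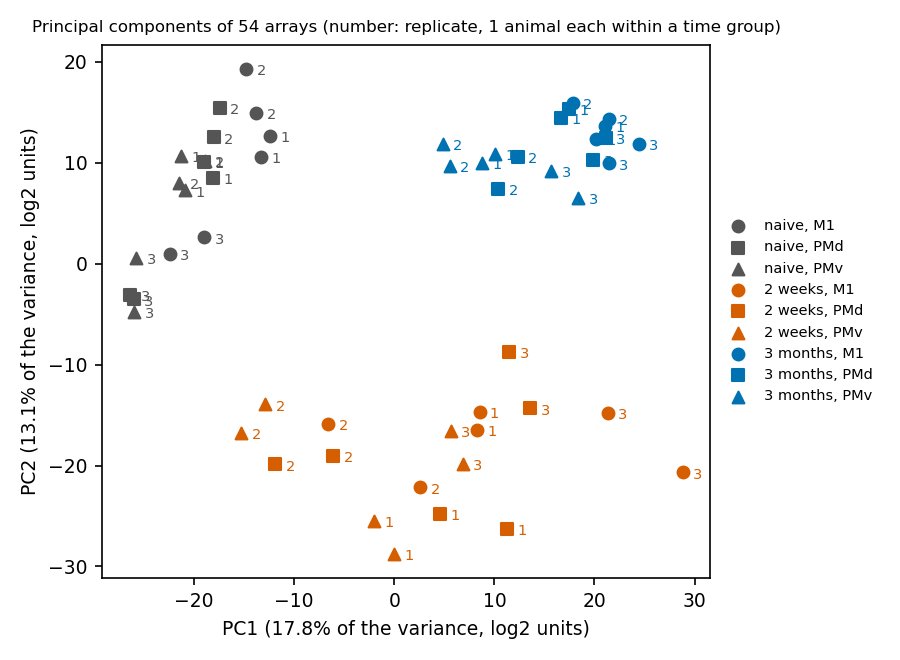
First principal component (x axis, 17.8% of the variance) against the second (y axis, 13.1%) of 54 arrays, in log2 units, with 1 point per array, colour for the time group, shape for the area and the replicate number beside each point. The 2-week arrays sit between −28.7 and −8.77 on the y axis, below all naive and 3-month arrays.

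Areas of intact cortex were compared first, to show how M1 differs from the premotor areas without a lesion. M1 differed from PMv in 1834 features, of which 919 were higher and 915 lower in M1, and it differed from PMd in 1257 features, of which 702 were higher and 555 lower (limma with the animal as a block, Benjamini-Hochberg adjusted p under 0.05). PMd and PMv differed in 1 feature, higher in PMd and well above background on 4 of 6 naive PMd arrays and 2 of 6 naive PMv arrays, with 1050 features at an unadjusted p under 0.05. It was not called with normexp background correction, where 1 other feature was, and it did not pass the stricter filter on dim probes or the filter on the naive arrays alone, where 4 others each were called. Most differences between M1 and the premotor areas were small. The median fold of the called features was 1.25 for M1 against PMd and 1.23 for M1 against PMv, and of those well above background on every array compared, 4 of 1162 and 19 of 1701 exceeded 2-fold. The number of calls fell whichever naive animal was left out, which also leaves fewer naive animals to compare. Without naive animal 1, 2 or 3 it was 226, 712 or 369 for PMd and 895, 824 or 646 for PMv, and with normexp background correction it was 672 and 1045. In each naive animal M1 lay on another slide than PMd and PMv, which shared 1 slide.

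The differences of M1 from the premotor areas were seen again in the lesioned animals, which entered the choice of features only through the filter, the choice of probes and the shared estimate of the spread. Of the 1257 features that differed between M1 and PMd in naive animals, 1140 (90.7%) had the same direction in the mean of the 2-week animals and 1177 (93.6%) in the mean of the 3-month animals, where 50% would follow from chance. Their median difference in the naive direction was 0.32 log2 in naive, 0.20 in 2-week and 0.20 in 3-month animals. For M1 against PMv the corresponding shares of the 1834 features were 98.1% and 97.9%, with median differences of 0.30, 0.33 and 0.29 log2. M1 and PMv lay on different slides in all 9 animals, so a difference between slides cannot be told apart from the area for this pair. Features are not independent of one another, and calls in naive animals were picked for their size there, so no p-value is attached to these shares. With filter, probes and spread taken from the naive arrays alone, 2070 features differed between M1 and PMd and 2574 between M1 and PMv (13543 tested). Of these 85.3% and 95.4% had the same direction in the 2-week animals and 82.4% and 94.3% in the 3-month animals.

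Left and right hemispheres of naive animals did not differ in any feature after adjustment (limma on the left minus right difference of each animal, 0 calls, 1407 at an unadjusted p under 0.05). All left pieces lay on odd and all right pieces on even positions of the slides, so side and position cannot be told apart.

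The response to the lesion was tested first on the mean of the 6 areas of each animal. At 2 weeks 65 of 14008 features differed from naive animals, 33 higher and 32 lower (limma, adjusted p under 0.05, 3 animals per group), and 2799 features (20.0%) had an unadjusted p under 0.05. The called features changed by a median of 1.59-fold, and 7 of the 51 that were well above background on every array of both groups changed by more than 2-fold. The count fell to between 0 and 29 when any one of the 9 animals was left out, and to 1, which was not among the 65, without the filter on dim probes (19371 features tested). The naive arrays, all arrays of 2-week animal 2 and the M1 arrays of 2-week animal 1 were scanned on 1 day and the other 2-week arrays on another. With scan day as a factor no feature was called, but the comparison then rests mainly on 2-week animal 2, the 1 lesioned animal with all areas on the shared day. All of the 65 features kept their direction there, with a median change of 0.65 log2 against 0.67 and a median SE of 0.12 against 0.098. However, 2-week animal 2 had a part in choosing the 65, and in all 65 the 2-week and naive animals did not overlap. The kept direction therefore largely follows from that choice, and the size in part, so neither decides about scan day.

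The array files identify transcripts by accession and do not pair them with gene names. The features given by accession were ranked by their measured change, as in the rule fixed in advance. That rule set accessions aside to be counted, so giving these 4 departs from it. XR_011876 was higher at 2 weeks than in naive animals, at −2.70 ± 0.37 against −4.63 ± 0.12 log2 (SD, n = 3, limma adjusted p = 0.0388), a difference of 1.94 ± 0.18 log2 (SE) or 3.82-fold. It was also called at 3 months, by 1.95 log2 (limma adjusted p = 0.0419). NM_022350 was at least 1.64-fold higher at 2 weeks (limma adjusted p = 0.0469). It was not well above background on any of the 18 naive arrays and was above it on 16 of the 18 arrays at 2 weeks, so its rank rests on naive values at background and its bound is close to the median called fold of 1.59. NM_052860 was at least 3.48-fold lower at 2 weeks (limma adjusted p = 0.0469), being well above background on all 18 naive arrays and on 0 of the 18 at 2 weeks. NM_001927, a bright feature, fell by 1.06 ± 0.16 log2 (SE, limma adjusted p = 0.0469), from 2.28 ± 0.24 to 1.22 ± 0.28 (SD, n = 3), and stood at 2.08 ± 0.10 at 3 months. NM_022350, NM_052860 and NM_001927 were not called at 3 months. NM_022350 was then well above background on 0 of 18 arrays, and NM_052860 and NM_001927 differed from naive animals by −0.12 and −0.20 log2. With scan day as a factor none of the 4 was called, and XR_011876 and NM_001927 differed by 1.66 and −1.02 log2, mainly on the values of 1 lesioned animal.

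At 3 months the mean of the 6 areas differed from naive animals in 2 features, 1 higher and 1 lower, both of which were also called in the same direction at 2 weeks (limma, adjusted p under 0.05). Unadjusted p-values under 0.05 were about as frequent as at 2 weeks (2712 features, 19.4%). The 3-month and 2-week animals differed in 0 features after adjustment, with 1979 at an unadjusted p under 0.05 and a smallest limma adjusted p of 0.0725. The count of 2 was 367 with array weights (193 higher, 174 lower), 23 with quantile normalization, 10 with normexp background correction and 13 with the stricter filter on dim probes. It was 83 without 2-week animal 3, 17 without 2-week animal 2, 12 without 3-month animal 2 and 0 without 3-month animal 1 or 3. Without the filter on dim probes it was 0. All 3-month arrays were scanned on a day of their own, so scan day and 3 months after the lesion cannot be told apart.

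The changes at 2 weeks and 3 months were correlated across features, with r = 0.57 for the mean of 6 areas, where unchanged groups compared with the same naive animals gave 0.49 in simulation. The covariance was 0.0554 against a simulated 0.0193. In right PMd r was 0.63 (0.50 simulated), with a covariance of 0.0827 (0.0239 simulated). With different naive animals as controls at the 2 times, 1 for one time and 2 for the other, r averaged 0.26 over the 6 arrangements (0.17 to 0.32) for the mean of 6 areas and 0.35 (0.26 to 0.45) in right PMd, with covariances of 0.0318 and 0.0560. Part of the relation against the same controls may therefore come from sharing them. Genes are not independent replicates, and all naive arrays were scanned on 1 day.

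Each of the 6 areas was then compared with the same area of naive animals. Right PMd had the most called features, 337 at 2 weeks (150 higher, 187 lower) and 145 at 3 months (56 higher, 89 lower), with median folds of 1.60 and 1.71. 28 of the higher and 49 of the lower features were called at both times in right PMd, where independent lists would share 0.600 and 1.19 and simulated unchanged groups shared 0. The first leaves out the naive animals that both lists share, and the second leaves out any change, so neither is the overlap to expect here. Right M1 had 54 called features at 2 weeks (41 higher, 13 lower, median fold 2.20) and 7 at 3 months (5 higher, 2 lower). Left M1 had 1 and 0, left PMd 1 and 8, left PMv 1 and 0, and right PMv 0 and 7 called features at 2 weeks and 3 months (limma, adjusted p under 0.05). Where no feature was called, 2115 in left M1 at 3 months, 1858 in left PMv at 3 months and 1630 in right PMv at 2 weeks had an unadjusted p under 0.05. With background corrected by the normexp method the higher and lower calls were 127 and 128 in right PMd at 3 months, and 78 and 41 in right M1 at 2 weeks. The order of the areas depended on the processing. Without the filter on dim probes right PMd had 0 called features at both times and right M1 34 at 2 weeks, and in 1 fit of all 54 arrays right PMd had 1484 and right M1 2107 at 2 weeks. With array weights the counts at 3 months were 683 in right PMd, 285 in right M1 and 158 in left PMd.

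The 337 features of right PMd moved the same way in the other areas of the same animals. At 2 weeks 337 of them had the same direction in left PMd, 325 in left M1, 332 in right M1, 336 in left PMv and 335 in right PMv, with median changes of 0.54, 0.44, 0.51, 0.44 and 0.40 log2 against 0.68 in right PMd itself. The features were chosen in right PMd, which raises their size there. Over all features the median absolute change was 0.19 log2 in right PMd and 0.20 in right M1, and 0.16, 0.17, 0.14 and 0.15 in left PMd, left M1, left PMv and right PMv. The areas come from the same animals, so these are not independent tests. Arrays of 1 animal deviated together from their group means, with r between 0.52 and 0.89. Features chosen in right PMd could therefore share their direction elsewhere without a lesion, and the share to expect then was not computed. Leaving out 1 animal lowered the count of right PMd in every case. At 2 weeks it fell to 0 without naive animal 1 or 2-week animal 3, to 1 without naive animal 3 or 2-week animal 1, to 2 without naive animal 2 and to 8 without 3-month animal 1, and it was 208, 167 and 95 without 3-month animal 2, 2-week animal 2 and 3-month animal 3. At 3 months it lay between 0 and 66 when any one of the 9 animals was left out. The 54 features of right M1 at 2 weeks became 436 without 2-week animal 1, and between 6 and 20 without 2-week animal 2 or 3 or any naive animal. The mean spike-in level of the right M1 array, in log2 above its 75th percentile, was 1.63, 1.85 and 2.31 in 2-week animals 1, 2 and 3 and 1.42 to 1.56 in naive animals. With scan day as a factor 0 features were called in right PMd at 2 weeks and 8 in right M1, on 1 and 2 lesioned animals scanned with the naive arrays. The median change of the 337 features was then 0.63 log2 with a median SE of 0.16, against 0.68 and 0.11 without that factor, and that of the 54 was 1.12 against 1.14. The lesioned animals scanned with the naive arrays had a part in choosing these features, so the similar sizes follow in part from the choice.

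**Figure D2:**
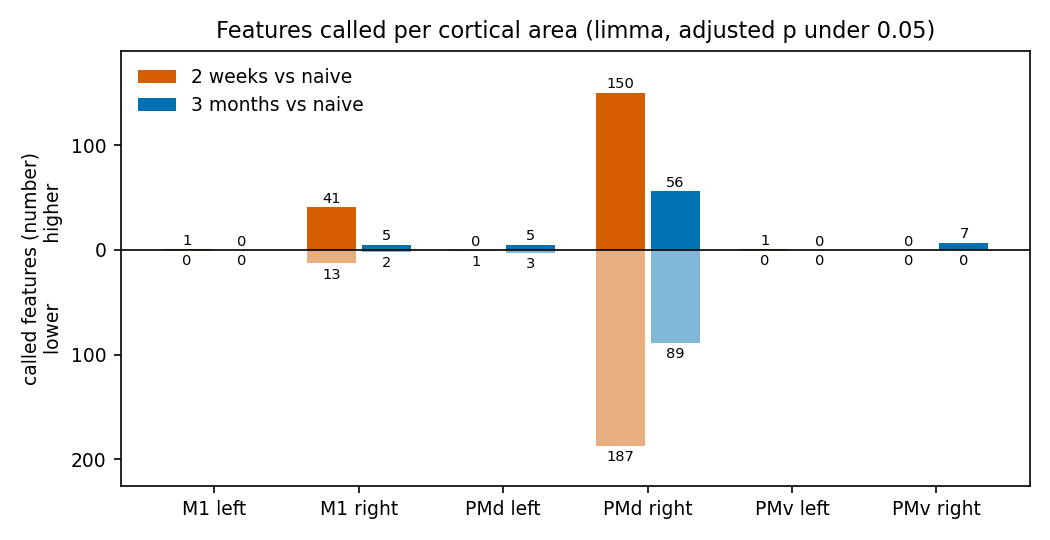
Number of features called against naive animals (y axis, higher above and lower below the 0 line) in each of 6 cortical areas (x axis) at 2 weeks (orange) and 3 months (blue), limma with adjusted p under 0.05 and 3 animals per group. Right PMd has the tallest bars, with 150 higher and 187 lower features at 2 weeks and 56 and 89 at 3 months.

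Whether the areas responded differently was tested with an area-by-time term. At 2 weeks the change differed among the 6 areas in 395 features and at 3 months in 3 (limma F test with the animal as a block, adjusted p under 0.05). Within the same model, the change at 2 weeks differed between M1 and the premotor areas in 949 features (421 more positive in M1, 528 more negative) and between PMd and PMv in 207. At 3 months these counts were 241 and 21, and the 241 fell to 0 without naive animal 1 or 3-month animal 1. For PMd against PMv, leaving out 1 animal gave 54 to 534 at 2 weeks and 1 to 170 at 3 months, and a split that mixed naive and 3-month animals gave 44 for the 21. The count of 949 ranged from 218 to 3017 when 1 animal was left out. Splits that mixed naive and 2-week animals gave 1301, 1115 and 649 for it, and 0 to 12 otherwise. The sizes were small, with a median of 0.26 log2 for the 949 features. This model counts the left and right arrays of an area as independent. With both treated as a correlated pair (estimated correlation 0.35), 116 features were called at 2 weeks for the 6 areas, 114 of them among the 395, with 87 for M1 against the premotor areas and 29 for PMd against PMv, and at 3 months 0, 0 and 2. With left and right averaged, the test over areas called 15 features at 2 weeks, 13 of them among the 395, and 0 at 3 months, and with the slide as a fixed factor 42 and 0, the latter over the 4 of 5 terms that could be estimated. With 1 value per animal, M1 against the premotor areas differed in 0 features at either time, and PMd against PMv in 11 at 2 weeks and 0 at 3 months. With normexp the counts of 949, 207, 241 and 21 were 456, 104, 26 and 3. The count of 395 was 2718 without 2-week animal 1, whose M1 was scanned on another day than its premotor areas, and 22, 53 and 16 without naive animal 1, 2 or 3. It was 196 without 2-week animal 3, 179 without 3-month animal 1 and 263 without 3-month animal 2. The count of 3 at 3 months was 91 without 2-week animal 1, 37 without 3-month animal 3, 24 without 3-month animal 1, 93 with scan day as a factor and 0 without naive animal 1 or 3 or 3-month animal 2, so the 2 times are not shown to differ in how many features vary by area.

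Left and right hemispheres were also compared in their response. The left minus right difference, averaged over M1, PMd and PMv, did not change in any feature at 2 weeks or at 3 months (limma, 0 calls each, smallest adjusted p of 0.0736 and 0.592). At 2 weeks 3160 features (22.6%) had an unadjusted p under 0.05 and at 3 months 822 (5.87%). In simulated data 89.6% of features whose left to right ratio, averaged over the 3 areas, changed 1.5-fold at 2 weeks were called. There the change was placed on the left side of every 2-week animal. The labels do not give the side of the lesion. If that side differed between animals, a change tied to it would partly cancel in the left minus right difference. The 0 calls therefore do not show that both hemispheres responded alike. The simulated arrays had independent noise, which leaves out any shift shared by the arrays of 1 side of an animal. Tested within M1, PMd or PMv alone, where the median SE was 0.12 log2 against 0.048 for the average and no simulation was run, 0 features were called at either time. In M1 this depended on 2-week animal 1. With all animals 1971 features had an unadjusted p under 0.05 in M1 at 2 weeks, and without that animal the left minus right difference changed in 1274 features after adjustment (606 more positive, 668 more negative), or in 736 with 1 value per animal. The spike-in level of M1 differed between left and right by −0.55 and −0.52 log2 in the 2 remaining 2-week animals, by 0.13 in the animal left out, by −0.060 to −0.0092 in naive animals and by −0.24 to 0.30 in 3-month animals. In PMd and PMv the count at 2 weeks stayed 0 without any one animal, and at 3 months it was 2 at most in any of the 3 areas.

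The spike-in control probes of the arrays stood higher above the 75th percentile of the array in the lesioned animals. The mean of 7 spike-in probes was 1.46 ± 0.12 log2 in naive, 1.81 ± 0.20 at 2 weeks and 2.01 ± 0.11 at 3 months (SD of animal means, n = 3). Each lesioned group differed from the naive group with p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 animals allow, and the lesioned groups differed from each other with an exact permutation p = 0.3. Among the arrays of 2-week animals the mean was 1.63 on the 8 scanned with the naive arrays and 1.95 on the 10 scanned on another day.

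**Figure D3:**
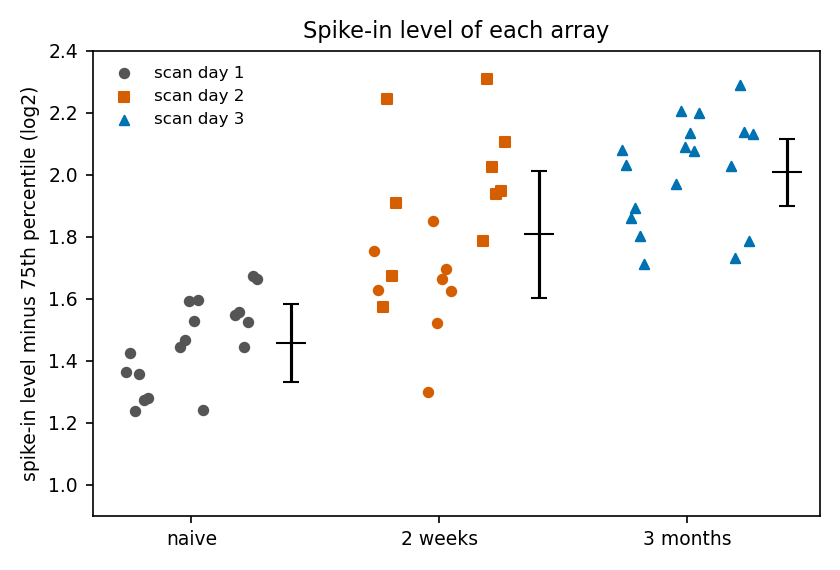
Spike-in level of each of 54 arrays, as the mean of 7 spike-in probes minus the 75th percentile of the array (y axis, log2), by time group (x axis), with the 3 animals of a group side by side, shape for the scan day and black bars for the mean and SD of the 3 animal means. The means rise from 1.46 in naive to 1.81 at 2 weeks and 2.01 at 3 months.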

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

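The contrasts of M1 against the premotor areas and of PMd against PMv, the test of scan day, the test with 1 value per animal and the fit with left and right as a correlated pair were chosen after the results were seen.

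The change against naive animals was compared between areas in a test of that difference itself. At 2 weeks 395 features were called over the 6 areas, 949 for M1 against the premotor areas and 207 for PMd against PMv, and at 3 months 3, 241 and 21 (limma, adjusted p under 0.05, with left and right arrays counted as independent). With left and right as a correlated pair the counts were 116, 87 and 29 at 2 weeks and 0, 0 and 2 at 3 months. With left and right averaged the count over areas was 15 at 2 weeks and 0 at 3 months, and with the slide as a fixed factor 42 and 0, the latter over 4 of 5 terms. With 1 value per animal the last 2 tests gave 0 and 11 at 2 weeks and 0 and 0 at 3 months. The count of 949 was 3017 without 2-week animal 1, 284 without 2-week animal 3 and 218, 529 and 306 without naive animals 1, 2 and 3. It was reached in 3 of 10 splits of the same 6 animals, since 2 splits that mix naive and 2-week animals gave 1301 and 1115, so this count is not tied to the lesion by that comparison.

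The area-by-time differences at 2 weeks were weighed against 2 technical explanations. The scan day of 2-week animal 1 was tested, since its M1 was scanned with the naive arrays and its premotor areas were not. With scan day as a factor 97.5% of the 395 features were also called, when 1625 were called in all. Most of the 395 calls therefore did not need the M1 to premotor difference of that animal, which the factor takes up. For this difference the fit rests on the other 2-week animals, which had a part in choosing the 395. It also counts left and right arrays as independent, so the kept calls do not decide about scan day. The left and right arrays of an area, which the model counts as independent, may account for most of the 949 features. With 1 value of M1 minus the premotor areas per animal, 0% of the 949 were called, since the standard error at those features rose from a median of 0.067 to 0.082 log2 and rested on the spread of 9 animals, while the median change of 0.26 log2 stayed as it was by construction. Residuals of the left and right arrays of an area correlated with a median r of 0.064 against −0.25 for arrays of different areas of an animal, and with the correlation of such pairs estimated in the fit 87 of the 949 were called, so a difference in response between the areas stays open for those.

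The spike-in probes, which are not among the features tested for areas and times, stood 1.81 log2 above the 75th percentile at 2 weeks and 2.01 at 3 months, against 1.46 in naive animals.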

How the results depend on the processing

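The fits with scan day, with the slide as a random block, on the shared scan day alone, on the naive arrays alone and with left and right as a correlated pair, and the tests of M1 against the premotor areas, PMd against PMv and left against right within an area under every setting, were chosen after seeing the data. All others were planned. Counts below are of called features, and a count is given where it moved by over 1.5 times, or as a range over the animals left out. For the count at 2 weeks the mean of 6 areas stayed within 1.5 times of 65 under normexp, quantile normalization, the authors' value table, array weights, the mean of the probes of an accession and the stricter filter. The features were not all the same. Of the 65, 46 were among the 88 called with normexp. With the stricter filter, which left some of the 65 untested, 49 were among the 58 called. All 65 were among the 87 called with quantile normalization and the 65 called with the authors' value table. The authors' value table and the mean of the probes of an accession moved none of the counts they could give. The cause of a moved count was not tested unless it is named.

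Leaving out 1 animal at a time gave 0 to 29 for the mean of 6 areas, 0 to 2 for M1 left, 6 to 436 for M1 right, 0 to 5 for PMd left, 0 to 208 for PMd right, 0 to 4 for PMv left, 0 to 1 for PMv right, 16 to 2718 for area-by-time, 218 to 3017 for the change of M1 against the premotor areas, 54 to 534 for the change of PMd against PMv, 0 to 1274 for the left minus right change within M1 and 0 for the left minus right change within PMd and within PMv at 2 weeks, 0 to 83 for the mean of 6 areas, 0 to 6 for M1 left, 1 to 76 for M1 right, 0 to 26 for PMd left, 0 to 66 for PMd right, 0 to 2 for PMv left and the left minus right change within PMd, 0 to 13 for PMv right, 0 to 91 for area-by-time, 0 to 705 for the change of M1 against the premotor areas, 1 to 170 for the change of PMd against PMv and 0 to 1 for the left minus right change within M1 and the left minus right change within PMv at 3 months, and 0 to 1 for the mean of 6 areas at 3 months against 2 weeks, 226 to 1727 for naive M1 against PMd, 646 to 2326 for naive M1 against PMv, 1 to 7 for naive PMd against PMv and 0 to 2 for naive left against right, and 0 for the left minus right change averaged over areas at both times. A group is then left with 2 animals, and all groups share 1 estimate of the spread. Without 2-week animal 1 the counts rose to 436 in M1 right at 2 weeks and to 2718 and 91 for area-by-time at 2 weeks and 3 months, and from 0 to 1274 for the left minus right change within M1 at 2 weeks. Without 2-week animal 3 they rose at 3 months to 83 for the mean of 6 areas, 6 in M1 left and 76 in M1 right.

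Normexp background correction gave 10 for the mean of 6 areas, 4 for M1 right, 5 for PMd left, 255 for PMd right, 1 for PMv right and the left minus right change, 9 for area-by-time, 26 for the change of M1 against the premotor areas and 3 for the change of PMd against PMv at 3 months, 0 for M1 left and PMv left, 119 for M1 right, 750 for PMd right, 188 for area-by-time, 456 for the change of M1 against the premotor areas and 104 for the change of PMd against PMv at 2 weeks, and 672 for naive M1 against PMd, 1045 for naive M1 against PMv and 1 for naive left against right. Quantile normalization gave 23 for the mean of 6 areas, 1 for M1 left and 0 for PMv right at 3 months, and 3 for naive PMd against PMv. Without the filter on dim probes, when more features were tested, the counts were 1 for the mean of 6 areas, 0 for M1 left and PMd right, 34 for M1 right, 196 for area-by-time and 129 for the change of PMd against PMv at 2 weeks, and 0 for the mean of 6 areas, PMd left, PMd right and PMv right, 101 for the change of M1 against the premotor areas and 3 for the change of PMd against PMv at 3 months. With probes well above background on all 54 arrays they were 13 for the mean of 6 areas, 1 for M1 left, 2 for M1 right, 0 for PMv right and 8 for area-by-time at 3 months, 0 for PMv left at 2 weeks, and 4 for naive PMd against PMv and 1 for naive left against right. Array weights gave 367 for the mean of 6 areas, 1 for M1 left and PMv left, 285 for M1 right, 158 for PMd left, 683 for PMd right and 60 for PMv right at 3 months.

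Animals of different time groups share only a number, since the deviations of same-numbered animals correlated with r between −0.096 and 0.082, and 2 of 9 animals correlated best with their own number. With the replicate number as a block the counts were 0 for the mean of 6 areas, M1 left, PMd left, PMd right and PMv left and 6 for M1 right at 2 weeks, and 6 for the mean of 6 areas, 0 for M1 right, PMd left and PMv right and 9 for PMd right at 3 months, and no other count moved. In the tests between areas the animal itself is the block. Without that block, the counts were 0 for area-by-time at 2 weeks, 0 for area-by-time at 3 months, and 0 for naive M1 against PMd and naive PMd against PMv and 33 for naive M1 against PMv. With left and right averaged they were 15 for area-by-time at 2 weeks, and 0 for area-by-time at 3 months, with left and right as a correlated pair 116 for area-by-time, 87 for the change of M1 against the premotor areas and 29 for the change of PMd against PMv at 2 weeks, and 0 for area-by-time and the change of M1 against the premotor areas and 2 for the change of PMd against PMv at 3 months, and with the slide as a fixed factor 42 for area-by-time at 2 weeks, and 0 for area-by-time at 3 months, where only 4 of the 5 terms could be estimated. The average over all 9 animals, naive and lesioned, gave 3635 for M1 against PMd, 6019 for M1 against PMv and 1679 for PMd against PMv. These are not differences of naive animals alone. In 2-week animal 2 and in 3-month animals 2 and 3 PMd and PMv lay on different slides, so more animals, the lesion and slides are not separated there. With filter, probes and spread from the naive arrays alone the counts were 2070 for naive M1 against PMd and 4 for naive PMd against PMv.

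In 1 fit of 54 arrays with the animal as a random block (correlation 0.67), which draws its degrees of freedom from arrays and not from animals, the counts were 546 for M1 left, 2107 for M1 right, 649 for PMd left, 1484 for PMd right, 162 for PMv left, 257 for PMv right and 1328 for the mean of 6 areas at 2 weeks, 845 for M1 left, 1028 for M1 right, 1079 for PMd left, 1307 for PMd right, 403 for PMv left, 619 for PMv right and 1457 for the mean of 6 areas at 3 months, and 602 for the mean of 6 areas at 3 months against 2 weeks. With the slide as a random block they were 1496 for M1 left, 3026 for M1 right, 824 for PMd left, 1751 for PMd right, 393 for PMv left, 476 for PMv right and 3206 for the mean of 6 areas at 2 weeks, 1333 for M1 left, 1596 for M1 right, 1371 for PMd left, 1472 for PMd right, 449 for PMv left, 749 for PMv right and 3085 for the mean of 6 areas at 3 months, and 1648 for the mean of 6 areas at 3 months against 2 weeks. With the animal as a random block and scan day as a factor they were 260 for M1 left, 1201 for M1 right, 124 for PMd left, 513 for PMd right, 38 for PMv left, 51 for PMv right and 291 for the mean of 6 areas at 2 weeks. Scan day as a factor in the separate fits, where the 2-week comparisons rest on 1 lesioned animal in PMd and PMv, 2 in M1 and mainly 1 for the mean, gave 0 for the mean of 6 areas, M1 left, PMd left, PMd right and PMv left, 8 for M1 right, 1625 for area-by-time, 2782 for the change of M1 against the premotor areas and 347 for the change of PMd against PMv at 2 weeks, and 93 for area-by-time, 667 for the change of M1 against the premotor areas and 54 for the change of PMd against PMv at 3 months. The arrays of the shared scan day alone, 1 or 2 lesioned animals, gave 0 for the mean of 6 areas, M1 left, PMd left, PMd right and PMv left and 7 for M1 right at 2 weeks, and a lone animal is there assumed to vary like the others.

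The 4 features named by accession kept their direction under each alternative that tested them. XR_011876 was no longer called in 11 of 22 alternatives, NM_022350 in 15 of 21, NM_052860 in 13 of 21 and NM_001927 in 14 of 22. The slide as a fixed factor was not run for the comparisons of time groups, since each slide held 1 time group. The tests of gene lists and their alternatives were not run for lack of gene names. Signal over background limits dim features, and NM_022350 and NM_052860 have only a bound in 1 of the groups compared.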

Other observations

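The reading of 2-week changes in the animal scanned with the naive arrays, the fit with scan day as a factor, the choice of features on the naive arrays alone and the contrasts of M1 against the premotor areas and of PMd against PMv were chosen after the data were seen.

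The features called in right PMd at 3 months also moved alike in the other areas of the same animals. Of the 145 features, 145 had the same direction in left PMd, 145 in right M1, 141 in left M1, 144 in left PMv and 142 in right PMv. The areas share the same animals, whose arrays deviated together, so these are not independent tests. The shares to expect without a lesion were not computed. Their median change in that direction was 0.78 log2 in right PMd, 0.66 in left PMd, 0.60 in right M1, 0.54 in left M1, 0.55 in left PMv and 0.54 in right PMv. The choice of features in right PMd raises their size there. Over all features the median absolute change at 3 months was 0.175 log2 in right PMd and between 0.143 and 0.171 in the other areas. Right PMd also had the lowest median spread between animals, with a residual SD of 0.172 log2 against 0.186 in right M1, 0.184 in left PMd, 0.181 in left M1, 0.178 in right PMv and 0.173 in left PMv.

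The differences between M1 and PMd in naive animals were weighed against a difference between slides, since these areas lay on different slides in naive animals. In the 3 lesioned animals whose M1 and PMd shared a slide, 92.6% of the 1257 features had the naive direction, and 81.6% of the 2070 features chosen on the naive arrays alone, which argues against slides as the whole cause. In the same 3 animals PMd and PMv lay on different slides and differed in 836 features, against 221 for M1 and PMd on 1 slide and 1 for PMd and PMv of naive animals on 1 slide, so slides may add to the number of calls. A difference between M1 and PMd stays open as the source of the shared directions. The 3 animals had been lesioned, so an effect of the lesion on PMd or PMv was not separated from the slide there.

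The 2-week changes of the mean of 6 areas were weighed against scan day. In 2-week animal 1 the difference between the premotor areas (second day) and M1 (first day), set against the other animals, followed the direction of the 65 called features with a median of 25.3% of their change, and the same value in the other 8 animals lay between −9.23% and 13.7%. This is above the other animals and below the change itself, so a part played by scan day cannot be told apart from a response to the lesion. Without 2-week animal 2, which was scanned with the naive arrays, 29 features were called, and 28 of them had the same direction in that animal, with a median change of 0.52 log2 against 0.94 in the other 2-week animals. With scan day as a factor the 65 features changed by a median of 0.65 log2 (median SE 0.12) against 0.67 (0.098), and 0 were called, as the SE rose. That fit rests mainly on the same animal, which had a part in choosing the 65. The same naive animals enter both readings, and 1 animal excludes nothing.

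Other splits of the same animals gave fewer calls than the real split for most results, but the 10 splits of 3 against 3 animals, or the 4 swaps within 3 naive animals, are too few for a share under 0.05. The real count was matched by no other split (1 of 10) for the mean of 6 areas at 2 weeks (65, highest other 0), left M1 (1 and 0), right M1 (54 and 0), right PMd (337 and 1) and left PMv (1 and 0) at 2 weeks, and for right M1 (7 and 3), left PMd (8 and 2), right PMd (145 and 2) and right PMv (7 and 2) at 3 months. The same held for the change differing among the 6 areas at 2 weeks (395 and 5), for PMd against PMv at 2 weeks (207 and 1) and for M1 against the premotor areas at 3 months (241 and 2). In 2 of 10 splits the count was at least as large for left PMd at 2 weeks (1 and 1), for the 6 areas at 3 months (3 and 3) and for PMd against PMv at 3 months (21 and 44). In 3 of 10 it was at least as large for the mean of 6 areas at 3 months (2 and 3) and for M1 against the premotor areas at 2 weeks (949 and 1301). The split with 1301 set naive animal 1 and 2-week animals 2 and 3 against naive animals 2 and 3 and 2-week animal 1. The mixed splits with 1115 and 649 also set 2-week animals 2 and 3 against 2-week animal 1, and all other mixed splits gave 0 to 12. M1 of 2-week animal 1 was scanned on another day than its premotor areas. What sets these splits apart was not tested, and the model counts left and right arrays as independent. Counts of 0 were matched by all 10 splits for the mean of 6 areas at 3 months against 2 weeks (highest other 2), left M1 and left PMv at 3 months (2 each), right PMv at 2 weeks (2), and the left minus right change at 2 weeks (7) and 3 months (0). Swapping areas within a naive animal gave 0 calls at most for M1 against PMd (1257), M1 against PMv (1834) and PMd against PMv (1), each reached in 1 of 4 swaps, and for left against right the count of 0 was reached in all 4, with 1 as the highest other.

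In 442 of the 14008 features 1 animal was well above background on all of its 6 arrays and another on none of its own. In 16 features every animal was of 1 of these kinds, and in 10 of the 16 a single animal was below background. The filter on dim probes keeps features seen in whole groups, which leaves out most features seen in 1 animal alone. Of the 65 features called for the mean of 6 areas at 2 weeks, 4 were among the 442.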
